A study of Rattus norvegicus with 4 samples.

How the data were processed

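Total RNA was measured on 4 Affymetrix rat expression arrays, 2 from cells transduced with a human CD9 adenovirus and 2 from cells transduced with a LacZ adenovirus. Per the labels' protocols, rat aortic smooth muscle cells were grown in medium with 10% serum and infected at 80% confluence. They were replated 72 hours later on plates coated with fibronectin at 10 ug/ml, and RNA was extracted with TRIzol after 6 hours. Per the labels' protocols, biotin-labelled cRNA was prepared from 6 ug of total RNA. Per the series' design text, RNA of 3 plates was pooled for each array, and 2 transduction experiments gave 2 data sets that were compared for genes regulated in both.

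The deposited values were intensity values on a linear scale for 31099 probe sets per array. Per the submitters' processing notes the authors used MAS5, an Affymetrix method that subtracts background and mismatch signal and summarises the probes of each set. Its version is not given in the sources used here. In the deposited values the mean after trimming 2% at each end was 250.07, 250.08, 250.07 and 250.07, so the arrays had been scaled to a common mean. No further normalization between arrays was present. Signals ranged from 0.144, 0.243, 0.0993 and 0.341 to 17366, 30347, 13688 and 27503 in CD9 replicates 1 and 2 and LacZ replicates 1 and 2. Scaling by 1 factor per array leaves shifts that depend on brightness in place, and the summary of dim probe sets by MAS5 is noisy, so folds of dim probe sets are uncertain. Detection calls, scanner files and the human transgene's sequence were not used here.

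Fold changes were computed on log2(signal + 16), a pseudocount that understates the change of dim probe sets. The 57 control probe sets were left out, and the upper 60% of the other probe sets by mean over the 4 arrays were tested, which left 18625 with a mean signal of at least 66.7. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The number of arrays limits the precision. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so p-values come from limma's pooled spread. The labels call the arrays biological replicates but name no donors, so limma's p-values without a block measure the spread between experiments on passage 9 cells. A block by replicate number takes the difference between experiments out of that spread. Camera's p-values at a preset correlation compare a list's genes with other genes and do not measure the spread between experiments.

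The titles number the arrays 1 and 2 in each group, and the series' design text describes 2 transduction experiments, each with RNA pooled for the CD9 and for the LacZ cells. The number was therefore read as marking the experiment, which no label states word for word. As a check, the deviations of same-numbered arrays from their group means correlated at r = 0.46 across the tested probe sets, which are not independent replicates. A fit with the replicate number as a block was run as an alternative, with 1 residual degree of freedom per probe set before pooling. It is called the fit within replicate pairs.

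Probe sets were named from the platform annotation: 20826 had 1 gene symbol, 436 had several and were not named, and 9780 were not listed there. Entrez identifiers of 20758 of the named probe sets matched the RefSeq gene table of assembly GRCr8, which was used for names only and updated 0 symbols. The tested probe sets covered 10319 genes, each represented by its probe set with the highest mean. Coordinates are not given.

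Before the data were examined, 30 gene lists, the alternatives and the rule for named genes were fixed. The lists covered tetraspanins and their partners, smooth muscle states, adhesion and matrix, growth and stress signalling, cell cycle, metabolism, and markers of endothelial cells, leukocytes and fibroblasts. They held 2 symbols that could not be matched. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes. With an estimated correlation, camera takes its p-value on the residual degrees of freedom of the fit, as fry does. With 2 arrays per group these are so few that hardly any list could pass either test after adjustment. Not passing them therefore decides neither for nor against a list. The median of a list was also ranked among 10000 random lists matched on mean signal. The rule named Cd9, then per direction the 12 genes past adjusted p 0.05 with the largest fold. Where fewer passed, it took the 12 with the smallest unadjusted p among genes changed at least 1.5-fold the same way in both same-numbered pairs, passing over unnamed loci. It also named up to 4 members of each list with the smallest unadjusted p. Probe sets changed at least 1.5-fold the same way in both pairs were counted, after the approach in the series' design text.

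The alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter, the upper 40% of probe sets, the replicate block, eBayes without a trend, each array left out in turn, a threshold of 0.1, 1 probe set per gene, the mean of a gene's probe sets, a fold limit of 2 and crossed pairs. Combinations of the block with other settings were added after the data were seen. The scripts were tested on data simulated for CD9 versus LacZ with 50 of 18625 probe sets changed at each fold. Without the block the fit recovered 0% of 2-fold, 18% of 4-fold, 56% of 8-fold and 90% of 16-fold changes, and called 0 unchanged probe sets. With the block it recovered 44%, 88%, 100% and 100%, and called 9 unchanged probe sets. With no change simulated, 0 lists were called in either fit, and the block called 1 probe set. The simulated noise was independent between probe sets, and its spread was set by brightness alone. The simulation therefore cannot show how often camera calls lists of correlated genes (estimated correlation 0.124 for immediate early and 0.551 for ribosomal genes). Nor can it show how the block recovers changes where probe sets of like brightness differ in spread.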

Results

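Gene expression was profiled in rat aortic smooth muscle cells, the contractile cells of the arterial wall, isolated from Sprague-Dawley rats. The cells were transduced with an adenovirus carrying human CD9 or, as a control, an adenovirus carrying LacZ, which encodes a bacterial beta-galactosidase. CD9 is a tetraspanin, a membrane protein that associates with integrins and growth factor precursors at the cell surface. Transduced cells were left to adhere to fibronectin, an integrin-binding matrix protein, for 6 hours before RNA was taken. Each group held 2 arrays from 2 transduction experiments, and the same replicate number was read as the same experiment. The question was which transcripts differ in adhering smooth muscle cells that carry the CD9 virus. The median signal was 99.9 and 100.4 in CD9 replicates 1 and 2, and 106.3 and 113.7 in LacZ replicates 1 and 2.

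Rat Cd9 (probe set 1371499_at) had signals of 516 and 788 in the CD9 arrays and 704 and 696 in the LacZ arrays. The log2 fold change of Cd9 was −0.13 ± 0.31 (SE, n = 2 per group; limma adjusted p = 1.00), and 0.17 without CD9 replicate 1. The transgene is a human cDNA, and whether the rat probes read it is not known here, so this value checks neither the labels nor the overexpression.

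Immediate early genes, which are transcribed within minutes of growth factor, adhesion or stress signals, formed the gene list with the smallest p in camera at the preset correlation, and their median was higher in the CD9 arrays. Fosb, which encodes a subunit of the AP-1 transcription factor, had signals of 1846 and 1204 in the CD9 arrays and 257 and 20.0 in the LacZ arrays. Its fold was 15.2, or 3.93 on the log2 scale (± 0.84, SE, n = 2 per group). With LacZ replicate 2 that dim, the size of the change is uncertain: the log2 fold change was 4.34 with a pseudocount of 1 and 3.24 with 64. Fos, another AP-1 subunit, had signals of 4189 and 1864 against 1281 and 229, a fold of 4.99 (log2 2.32 ± 0.76). Egr1, a zinc finger transcription factor, had signals of 4518 and 4485 against 1761 and 975.3, a fold of 3.40 (log2 1.77 ± 0.34). In pairs 1 and 2 the log2 fold changes were 2.77 and 5.08 for Fosb, 1.70 and 2.94 for Fos, and 1.35 and 2.18 for Egr1. The SEs above are those without the block. With the block, whose spread is pooled across probe sets, they were smaller, at 0.37, 0.24 and 0.19. In each of these genes the pairs lay farther apart than the SE with the block implies. The p-values with the block therefore rest mainly on the spread of other probe sets of like brightness, not on the spread between the gene's own pairs. Fosb, Fos and Egr1 rose within the replicate pairs (limma with the replicate block, adjusted p = 0.000161, 0.000231 and 0.000300), each higher in 2 of 2 pairs. Without the block none of them passed (adjusted p = 1.00 each), and with the block but no intensity trend 0 probe sets passed. Without LacZ replicate 1, the array in which Fosb was brighter of the LacZ arrays, Fosb passed without the block (log2 fold change 5.39, adjusted p = 0.00477), and without LacZ replicate 2 its log2 fold change was 2.46. That of Fos was 3.52 without LacZ replicate 1 and 1.12 without LacZ replicate 2. A dimmer Fos probe set outside the tested range (1371283_at) had signals of 14.6 and 41.3 in the CD9 arrays and 52.6 and 82.4 in the LacZ arrays. Nr4a1, an orphan nuclear receptor, had a log2 fold change of 1.09 ± 0.30, and Klf4, a transcription factor of smooth muscle dedifferentiation, 0.84 ± 0.29. Neither passed over all genes in either fit.

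Of the 32 measured immediate early genes, 24 had a higher and 8 a lower mean log2 signal in the CD9 arrays, and 22 were higher in both pairs. The list's median log2 fold change was 0.43 as deposited, 0.35 after quantile normalization and 0.54 after median centring, and it passed camera (adjusted p = 9.37e-10). It did not pass with an estimated correlation (adjusted p = 0.901) or by fry (adjusted p = 0.736). With 2 arrays per group both tests have few residual degrees of freedom, so hardly any list could pass them. Adjusted over the list alone, 2 members, Egr1 and Fosb, rose without the block, and 14 rose with it. Over all genes the counts were 0 and 3. Signs of RNA quality differed in the same direction as this list. The 3'/5' signal ratio of hexokinase, which is higher where RNA is degraded or copied incompletely, was 6.13 and 10.8 in the CD9 arrays and 2.60 and 4.90 in the LacZ arrays. The ratio of Gapdh was 1.22 and 2.10 against 0.977 and 1.57, and that of actin 1.49 and 1.68 against 1.22 and 0.965.

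**Figure D1:**
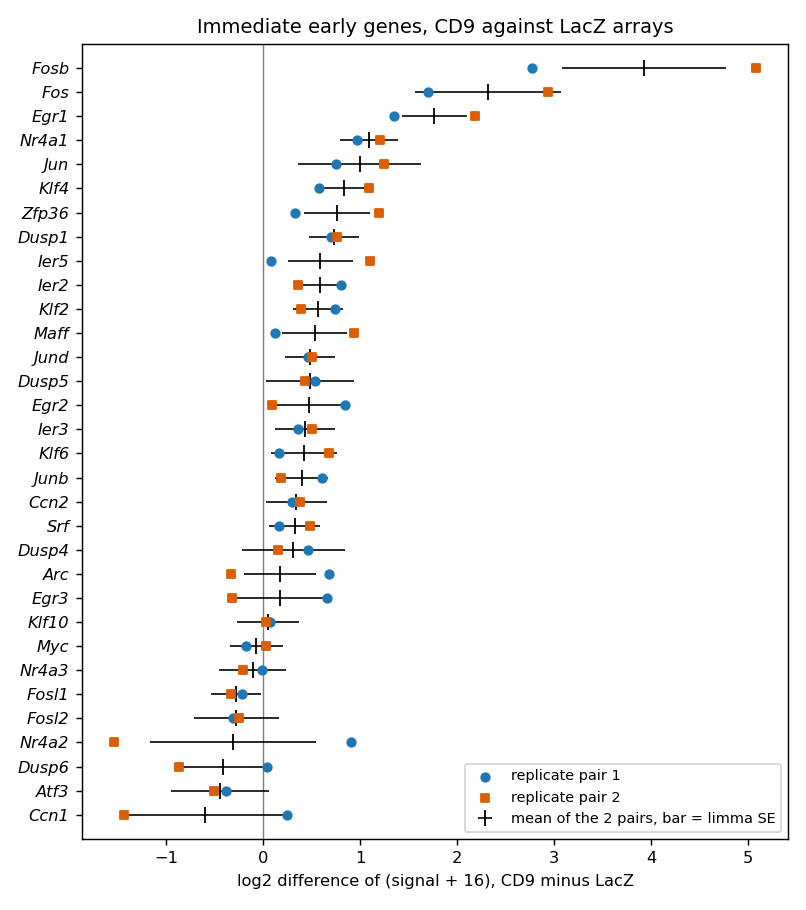
Log2 difference in signal between CD9 and LacZ arrays for the 32 measured immediate early genes, on the log2(signal + 16) scale of the horizontal axis. Circles and squares are replicate pairs 1 and 2, and the vertical tick with its bar is the mean and limma's SE; Fosb, Fos and Egr1 lie farthest to the right, at means of 3.93, 2.32 and 1.77.

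Over the 18625 probe sets tested, 0 passed limma without the block, 227 had an unadjusted p under 0.05 (59 higher and 168 lower in the CD9 arrays), and 931 would be expected by chance. Within the replicate pairs 4 passed, 4 higher and 0 lower, and 1317 had an unadjusted p under 0.05 (574 higher, 743 lower). Under other settings of that fit lower ones passed too, 11 of 25 after quantile normalization and 20 of 41 with the upper 40% of probe sets. The 4 were those of Fosb, Fos and Egr1 and an unnamed one, 1391674_at, named here after its values were seen. Its signals were 694 and 854 in the CD9 arrays and 262 and 255 in the LacZ arrays (log2 fold change 1.52 ± 0.29; adjusted p = 0.0251 within pairs). At a threshold of 0.1 within pairs, 6 passed. The additional ones were Hes1 and Clic4, a chloride intracellular channel protein chosen after its values were seen, with a log2 fold change of −1.13 ± 0.36 and an adjusted p of 0.0687 within pairs.

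Other genes at least 1.5-fold higher in both pairs did not pass the test in either fit. Hes1, a transcriptional repressor induced by Notch, had signals of 1427 and 718 in the CD9 arrays and 515 and 325 in the LacZ arrays, a fold of 2.42 (log2 1.27 ± 0.41; adjusted p = 0.0574 within pairs; log2 0.79 without CD9 replicate 1). S100a13, a calcium-binding protein, had a fold of 2.82, with signals of 311 and 441 against 183 and 78.2 (log2 1.496, and 0.95 without LacZ replicate 2). RT1-Ba, a class II major histocompatibility chain, had a fold of 2.17, with signals of 154 and 214 against 73.3 and 76.7. A second RT1-Ba probe set had a log2 fold change of 2.00 and another −0.24. Dimmer genes were Stpg1 (fold 3.26), Tox3 (2.98), Art4 (2.81), Bend6 (2.58) and Setd6, a lysine methyltransferase (2.16), with mean signals of 37.1, 41.5, 34.0, 49.1 and 88.6 in the LacZ arrays. At such signals the folds depend on the pseudocount: the log2 fold changes were 1.70, 1.58, 1.49, 1.37 and 1.11 with 16, and 1.13, 1.06, 0.95, 0.91 and 0.84 with 64.

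The genes given here as lower, not all of those the rule named, had mean signals between 30.5 and 151 in the CD9 arrays, and none passed the test in either fit. Adam3a, a metalloprotease-disintegrin known from sperm, had signals of 26.3 and 34.7 in the CD9 arrays and 189 and 203 in the LacZ arrays, 4.57-fold lower (log2 −2.19 ± 0.44, n = 2 per group), but the log2 fold change was −2.65 with a pseudocount of 1 and −1.46 with 64. Sgpl1, the lyase that degrades sphingosine phosphate, had signals of 155 and 72.8 against 326 and 289, 2.62-fold lower (log2 −1.39, and −0.92 without CD9 replicate 2). F2rl1, a protease-activated receptor, had signals of 144 and 159 against 262 and 353, 1.91-fold lower. The other lower genes were Fmo1 (2.80-fold), a flavin monooxygenase, Them5 (2.81), Serpind1 (2.73), the thrombin inhibitor heparin cofactor, Rnf126 (2.66), a ubiquitin ligase, Cd300c2 (2.34), Cnga2 (2.24), a cyclic nucleotide-gated channel, Ikzf4 (2.18) and Dyrk1a (2.08), a protein kinase. These folds depend on the pseudocount: the log2 fold changes of Fmo1, Them5, Serpind1, Rnf126, Cd300c2, Cnga2, Ikzf4 and Dyrk1a were −0.97, −0.99, −0.93, −1.03, −0.89, −0.87, −0.82 and −0.85 with 64.

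Targets of YAP-TEAD and MRTF-SRF, transcription factors that respond to actin tension and adhesion, were higher as a list in the CD9 arrays. The median log2 fold change of its 23 measured members was 0.32 as deposited, 0.18 after quantile normalization and 0.44 after median centring, and 17 were higher in both pairs. The list passed camera (adjusted p = 9.51e-05) but not with an estimated correlation (adjusted p = 0.901), nor by fry (adjusted p = 0.416), nor without LacZ replicate 2 (adjusted p = 0.0754). Its median was 0.17 without CD9 replicate 2. Tpm1, which encodes tropomyosin, had mean signals of 7719 ± 683 and 5363 ± 1481 (SD, n = 2) in the CD9 and LacZ arrays, and Axl, a receptor tyrosine kinase, 5564 ± 1121 and 4234 ± 30.9. Vcl, which encodes vinculin, had 8014 ± 2763 and 5772 ± 771, and F3, tissue factor, 1246 ± 139 and 892 ± 681. Acta2, smooth muscle alpha-actin, had 10537 ± 3553 and 7577 ± 3326. Adjusted over the list alone, 0 members passed without the block and 4 rose with it, among them Tpm1, Acta2 and Vcl, and over all genes 0 passed in either fit. Single arrays moved these genes. The log2 fold change of Acta2 was 0.51, and 0.86, 0.16, 0.04 and 0.97 without CD9 replicates 1 and 2 and LacZ replicates 1 and 2. That of Vcl was 0.43, and 0.79 without CD9 replicate 1 and 0.08 without CD9 replicate 2. That of Tpm1 was 0.55, and 0.83 without LacZ replicate 1 and 0.26 without LacZ replicate 2. That of Axl was 0.38, and 0.58 and 0.17 without CD9 replicates 1 and 2. That of F3 was 0.71, and 1.56 and −0.14 without LacZ replicates 1 and 2. The list shared 3 members with the immediate early genes, and its other 20 members had a median of 0.31. The signs of RNA quality went with this list too: the 3'/5' ratios of hexokinase, actin and Gapdh were 2.28-, 1.46- and 1.29-fold higher in the CD9 arrays.

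Lists of matrix and adhesion genes had smaller medians. Extracellular matrix genes had a median log2 fold change of 0.18 over 35 members, 25 of them higher (camera adjusted p = 0.0242; 0.07 after quantile normalization and 0.30 after median centring). The adjusted p was 0.901 with an estimated correlation, 0.935 by fry, 0.0565 without a trend and 0.910 after quantile normalization. Without CD9 replicate 1, CD9 replicate 2 or LacZ replicate 1 the matrix list did not pass (adjusted p = 0.129, 0.218 and 0.665; medians 0.28, 0.0042 and −0.07). Nid1, a basement membrane nidogen, had mean signals of 1728 ± 531 in the CD9 arrays and 978 ± 581 in the LacZ arrays (SD, n = 2). Lox, the collagen crosslinking enzyme, had 4909 ± 112 and 3581 ± 882, Col11a1, a fibrillar collagen chain, 721 ± 113 and 490 ± 74.8, and Postn, the matricellular protein periostin, 10076 ± 919 and 7442 ± 991. Focal adhesion and actin cytoskeleton genes had a median of 0.11 over 31 members, 24 of them higher (camera adjusted p = 0.0344; 0.01 after quantile normalization and 0.23 after median centring). That list's adjusted p was 0.901 with an estimated correlation, 0.935 by fry, 0.0716 without a trend, 0.698 with the mean of each gene's probe sets and 0.826 after quantile normalization, and without any 1 of the arrays it did not pass (adjusted p between 0.0754 and 0.437; medians between 0.0094 and 0.24). Tns1, which encodes tensin, had 2561 ± 242 and 1616 ± 440, and Msn, which encodes moesin, 6746 ± 642 and 5129 ± 853. Dimmer probe sets went the other way for Msn (log2 fold change −1.16), Nid1 (−0.41), Tns1 (−0.22) and Col11a1 (−0.18), and of 2 dimmer Vcl probe sets 1 did (−0.27) and 1 did not (0.51). Adjusted over the list alone, 1 matrix gene, Nid1, and 0 adhesion genes rose within pairs, 0 passed in either list without the block, and over all genes 0 passed in either fit. The log2 fold change of Nid1 was 0.91, and 0.60 without CD9 replicate 1, 1.54 without LacZ replicate 1 and 0.28 without LacZ replicate 2. That of Lox was 0.48, and 0.73 without LacZ replicate 1 and 0.22 without LacZ replicate 2, and those of Tns1 and Msn were 0.68 and 0.40, and 0.40 and 0.23 without LacZ replicate 2.

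Ribosomal protein genes had a median log2 fold change of 0.18 over 28 members as deposited and 0.29 after median centring, but −0.03 after quantile normalization. It was −0.03 without LacZ replicate 1 (adjusted p = 0.923), 0.04 without CD9 replicate 2 (adjusted p = 0.752) and 0.42 without LacZ replicate 2. As deposited, 26 of the 28 had a higher mean log2 signal in the CD9 arrays. The list passed camera as deposited (adjusted p = 0.0179) but not with an estimated correlation (adjusted p = 0.901), by fry (0.935), after quantile normalization (0.346) or with no filter on low values (0.0629). Rps29 had mean signals of 13024 ± 2347 and 9842 ± 602, and Rpl26 14419 ± 3988 and 11225 ± 2011 (SD, n = 2). The log2 fold change of Rps29 was 0.39, and 0.21 without CD9 replicate 2, and that of Rpl26 was 0.34, and 0.63, 0.06, 0.16 and 0.53 without CD9 replicates 1 and 2 and LacZ replicates 1 and 2. In all tested probe sets the fold change moved with brightness: the median log2 fold change was −0.12 in the 3725 dimmest of them (median signal 83.7) and 0.09 in the 3725 brightest (median signal 1111). The median signal of the ribosomal list was 9690, of the YAP-TEAD and MRTF-SRF list 2591, of the matrix list 3110, of the adhesion list 1814 and of the immediate early list 763.

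Genes of the G1/S transition and DNA replication were the only list past camera at the preset correlation that was lower in the CD9 arrays. Their median log2 fold change was −0.15 as deposited, −0.13 after quantile normalization and −0.03 after median centring. Of 42 members 30 had a lower mean log2 signal, and 16 were lower in both pairs (camera adjusted p = 0.0179; adjusted p = 0.901 with an estimated correlation). The call was lost after quantile normalization (adjusted p = 0.103), with no filter on low values (adjusted p = 0.124), without a trend (adjusted p = 0.0565), with the mean of each gene's probe sets (adjusted p = 0.139), by fry (adjusted p = 0.935), without CD9 replicate 1 (median −0.05, adjusted p = 0.213) and without LacZ replicate 2 (median 0.02, adjusted p = 0.527). Without LacZ replicate 1 the median was −0.35. Ccne2, the S-phase cyclin E family member, had mean signals of 61.7 ± 44.5 in the CD9 arrays and 120 ± 16.3 in the LacZ arrays (SD, n = 2). Prim1, a DNA primase subunit, had 308 ± 64.3 and 443 ± 76.1, and the replicative helicase subunits Mcm6 and Mcm5 had 246 ± 24.0 and 346 ± 4.39, and 165 ± 12.7 and 296 ± 161. The log2 fold change of Ccne2 was −0.93, and −1.55 and −0.31 without CD9 replicates 1 and 2, and that of Mcm5 −0.69, and −1.24 and −0.13 without LacZ replicates 1 and 2. That of Prim1 was −0.50, and −0.30 without CD9 replicate 2 and −0.33 without LacZ replicate 2. Adjusted over the list alone, and over all genes, 0 ribosomal and 0 G1/S genes passed in either fit.

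**Figure D2:**
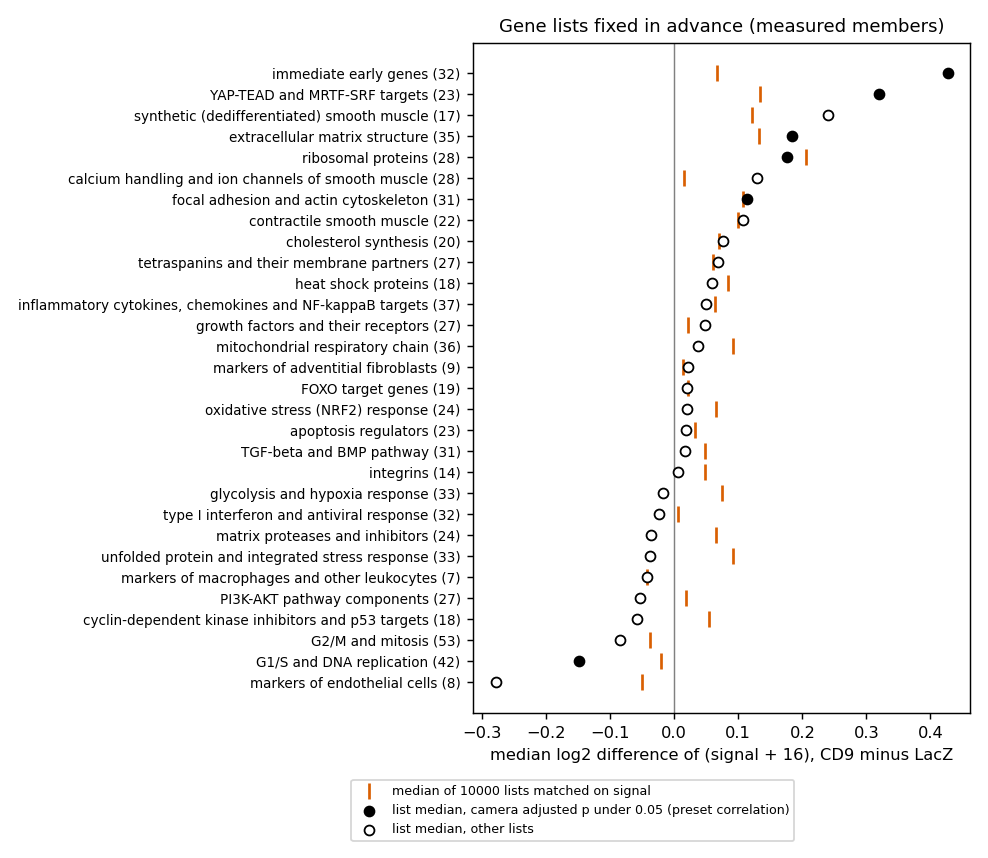
Median log2 difference in signal between CD9 and LacZ arrays for the 30 gene lists, with the number of measured members after each name. Filled circles are lists past camera at the preset correlation, open circles the other lists, and vertical ticks the median of 10000 random lists matched on signal; the immediate early list lies at 0.43 against a matched 0.07, while the ribosomal list lies at 0.18 against a matched 0.21, and at −0.03 after quantile normalization.

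The lists of smooth muscle states did not pass camera, but 1 of them lay close to the threshold. Synthetic, or dedifferentiated, smooth muscle genes had a median log2 fold change of 0.24 over 17 members (adjusted p = 0.0511) and passed within pairs (adjusted p = 0.00198), where the adjusted p was 0.743 with an estimated correlation. Without the block it passed with a pseudocount of 64 (adjusted p = 0.0428), median centring (0.0426), the upper 40% of probe sets (0.0272) and the mean of each gene's probe sets (0.0126). After quantile normalization its median was 0.06 (adjusted p = 0.668), and without LacZ replicate 1 it was −0.01. Klf4 rose within pairs adjusted over that list alone, and Pdgfra, a growth factor receptor, had mean signals of 724 ± 70.3 and 502 ± 57.9 in the CD9 and LacZ arrays. Contractile genes had a median of 0.11 over 22 members (adjusted p = 0.459), and Tpm1 and Acta2 rose within pairs adjusted over the list alone, but Tpm1 had a log2 fold change of 0.26 without LacZ replicate 2 and Acta2 0.04 without LacZ replicate 1. Lmod1, a leiomodin, had 597 ± 141 and 371 ± 29.9, and Kcnmb1, a potassium channel subunit, 50.5 ± 17.5 and 97.8 ± 14.3. Their log2 fold changes were 0.65 and −0.79, and 0.41 and −0.52 without CD9 replicate 2. Calcium handling and ion channel genes had a median of 0.13 (adjusted p = 0.231), and passed with the upper 40% of probe sets (adjusted p = 0.0395). Cav1, which encodes caveolin, had 8000 ± 834 and 5646 ± 46.4, a log2 fold change of 0.50, but its dimmer probe sets had 0.11 and, lower in both pairs, −0.58.

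The lists closest to CD9 itself did not pass. Tetraspanins and their partners had a median log2 fold change of 0.07 (adjusted p = 0.671), and integrins 0.01 (adjusted p = 0.973). Of 14 integrins 7 were higher and 7 lower. Itga1 and Itgb5 had log2 fold changes of −0.43 and −0.50, and 0.03 and 0.01 in the first pair. Itga6 had 0.79, and 0.05 in the first pair, with dimmer probe sets at −0.53, −0.08 and −0.18. Itgb1, the beta chain shared by fibronectin receptors, had mean signals of 6080 ± 596 in the CD9 arrays and 4181 ± 1003 in the LacZ arrays, and it rose within pairs adjusted over the integrin list alone, with a log2 fold change of 0.56, and 0.31 without LacZ replicate 2. A dimmer Itgb1 probe set had 0.24, and −0.06 in the first pair. Cd44, a hyaluronan receptor, had 1854 ± 117 and 2436 ± 552, a log2 fold change of −0.37, and −0.14 and −0.61 without LacZ replicates 1 and 2. PI3K-AKT pathway components had a median of −0.05 (adjusted p = 0.913), FOXO targets 0.02 (adjusted p = 0.673) and growth factors and their receptors 0.05 (adjusted p = 0.834). Of the 27 PI3K-AKT members 16 were lower. Among them, Pik3r3 had a log2 fold change of −1.57, and −0.38 without CD9 replicate 2. Pik3r1 had −0.84, but 0.31 in the first pair. Irs2, an insulin receptor substrate, had mean signals of 544 ± 21.8 and 352 ± 70.6, and Klf2, a FOXO target that is also an immediate early gene, 3633 ± 140 and 2457 ± 328. Dimmer Klf2 probe sets had log2 fold changes of 0.18, 0.39 and −0.08, against 0.57. Matrix proteases and inhibitors had a median of −0.04 (adjusted p = 0.671). In the TGF-beta and BMP pathway (median 0.02; adjusted p = 0.619), Id1, a BMP target, had 1146 ± 267 and 549 ± 122, and Grem1, a BMP antagonist, 8081 ± 551 and 5808 ± 707. Both rose within pairs adjusted over the list alone, as Klf2 did over the FOXO list, and 0 of these genes passed over all genes in either fit.

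Of the proliferation and survival lists, G2/M and mitosis had a median log2 fold change of −0.08 (adjusted p = 0.470), apoptosis regulators 0.02 (adjusted p = 0.459) and cyclin-dependent kinase inhibitors and p53 targets −0.06 (adjusted p = 0.459). Without CD9 replicate 2 the G2/M list (median −0.26, adjusted p = 0.000636) and the list of kinase inhibitors and p53 targets (−0.32, adjusted p = 0.0189) passed, but their medians were 0.19 and 0.17 without CD9 replicate 1, and 0.10 and 0.16 without LacZ replicate 2. Birc5, the mitotic and antiapoptotic protein survivin, had mean signals of 99.2 ± 19.7 in the CD9 arrays and 205 ± 14.6 in the LacZ arrays. Gdf15, a stress-induced cytokine, had 196 ± 152 and 529 ± 557, and it fell within pairs adjusted over its list alone, with a log2 fold change of −1.04, and −0.24, −1.85, −2.36 and 0.28 without CD9 replicates 1 and 2 and LacZ replicates 1 and 2. Inflammatory and NF-kappaB genes had a median of 0.05 (adjusted p = 0.619) and interferon response genes −0.02 (adjusted p = 0.636). Nos2, the inducible nitric oxide synthase, had 61.8 ± 59.4 and 195 ± 22.9, with a log2 fold change of −1.68, and −2.55 and −0.81 without CD9 replicates 1 and 2. Of the metabolic lists, cholesterol synthesis had a median of 0.08 (adjusted p = 0.231), glycolysis and hypoxia −0.02 (adjusted p = 0.878) and the mitochondrial respiratory chain 0.04 (adjusted p = 0.836). The mitochondrial list passed without LacZ replicate 2 (median 0.30, adjusted p = 0.00288), but its median was −0.18 without LacZ replicate 1 and −0.14 without CD9 replicate 2. Msmo1, a sterol oxidase, had 6940 ± 495 and 5046 ± 226, and Srebf2, the regulator of sterol synthesis, 2570 ± 1267 and 1582 ± 374, and both rose within pairs adjusted over the cholesterol list alone. The log2 fold change of Srebf2 was 0.62, and 1.14, 0.10 and 0.38 without CD9 replicates 1 and 2 and LacZ replicate 1.

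Of the stress lists, the unfolded protein and integrated stress response had a median log2 fold change of −0.04 (adjusted p = 0.123), and −0.15 after quantile normalization, where it passed (adjusted p = 0.000371), as it did with the upper 40% of probe sets (adjusted p = 0.0272). Sesn2, a stress-induced regulator of mTOR, had mean signals of 1188 ± 16.02 in the CD9 arrays and 1671 ± 147 in the LacZ arrays, a log2 fold change of −0.48. A dimmer Sesn2 probe set had 0.00039, with 0.26 and −0.26 in pairs 1 and 2. Creld2 and Ddit3, induced by endoplasmic reticulum stress, had 1037 ± 99.7 and 1705 ± 994, and 403 ± 83.4 and 609 ± 300. The log2 fold changes of Creld2 and Ddit3 were −0.58 and −0.50, and 0.05 and 0.0063 without LacZ replicate 2, −1.21 and −1.01 without LacZ replicate 1, and −0.30 for Ddit3 without CD9 replicate 1. Heat shock proteins had a median of 0.06 (adjusted p = 0.958) and the NRF2 response 0.02 (adjusted p = 0.671). Markers of other cell types were measured for few members: 8 endothelial markers had a median of −0.28 (adjusted p = 0.123, and 0.0453 with a pseudocount of 64; median −0.15 without CD9 replicate 1, −0.64 and 0.18 without LacZ replicates 1 and 2, and −0.02 with no filter), 7 leukocyte markers −0.04 (adjusted p = 0.973) and 9 fibroblast markers 0.02 (adjusted p = 0.836). Flt1, an endothelial growth factor receptor, had 103 ± 48.8 and 177 ± 34.0, with a log2 fold change of −0.76, and −1.19 and −0.32 without CD9 replicates 1 and 2. The median's sign differed from that of the mean for apoptosis (mean −0.09), inflammatory (−0.12) and fibroblast genes (−0.12), heat shock proteins (−0.0015) and leukocyte markers (0.0061), and from camera's direction for those lists except heat shock proteins, and for integrins.

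Across the 30 lists, 6 passed camera at the preset correlation, 5 higher and 1 lower, and 7 within replicate pairs. With an estimated correlation 0 passed, and 0 passed by fry, tests that hardly any list could pass with so few residual degrees of freedom. The 3'/5' ratios that differed between the groups apply to the matrix, adhesion, ribosomal and G1/S lists as they do to the other 2. Of the 24 lists that did not pass, 22 had a median that changed sign under at least 1 alternative other than median centring. Their medians are given as values, without calling a direction. Of the lists that passed, the ribosomal median changed sign under 2 alternatives, and the matrix and G1/S medians under 1 each.

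By the approach of the series' design text, 509 probe sets were at least 1.5-fold different the same way in both same-numbered pairs, 121 higher and 388 lower in the CD9 arrays. Another 322 differed by as much in opposite directions, and 291 would be changed the same way if the pairs were independent (88.7 higher and 203 lower). Across the tested probe sets the log2 fold changes of the 2 same-numbered pairs correlated at only r = 0.076, and at r = −0.40 with the pairs crossed. With the pairs crossed, 489 differed the same way (124 higher and 365 lower) and 2583 in opposite directions. The split moved with the scaling: after quantile normalization it was 162 higher and 266 lower, and after median centring, which raised every log2 fold change by 0.12, it was 211 higher and 238 lower. The probe sets lower in both pairs had a median signal of 100.7 and those higher in both 91.9, against 227 over all tested. Same-numbered arrays resembled each other more than arrays of a group: Pearson's r across probe sets was 0.961 for the first pair and 0.914 for the second, 0.907 between the CD9 arrays and 0.871 between the LacZ arrays. Of the variance among the 4 arrays, 23.9% lay along the group, 55.6% along the replicate number and 20.6% along their interaction.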

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

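The 3'/5' ratios were planned, and the tests of the spike and ribosomal RNA controls were chosen only after the data were seen. These control probe sets were left out of the tests of genes and lists. The 3 ratios, the mean of the spike controls and the 5S signal were each higher in the CD9 array of both pairs. The hexokinase 3'/5' ratio was 2.36-fold higher in the first pair and 2.21-fold in the second, a geometric mean of 2.28. The 18 hybridisation spike controls, which are added from outside the cells, had geometric mean signals of 1385 and 1464 in the CD9 arrays and 918 and 1070 in the LacZ arrays, a 1.44-fold difference, with 17 of the 18 higher in both pairs. The control for 5S ribosomal RNA had signals of 71.97 and 133 in the CD9 arrays and 27.9 and 22.1 in the LacZ arrays, 2.58-fold and 6.04-fold in the pairs (geometric mean 3.95, with no pseudocount). The LacZ signals are dim, so the size of this difference is uncertain. The 3'/5' ratios of Gapdh and actin were 1.29-fold and 1.46-fold higher.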

How the results depend on the processing

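Settings that join the replicate block with another were chosen only after the data were seen, and the other alternatives were planned. The count of probe sets past limma was 0 under every alternative except the replicate block (4) and leaving out arrays, where it ranged from 0 to 1 (Fosb, without LacZ replicate 1, adjusted p = 0.00477). Within pairs, the 4 (0 lower) became 25 with quantile normalization (14 higher, 11 lower), 150 with median centring (107 and 43), 10 with no filter (6 and 4), 41 with the upper 40% of probe sets (21 and 20) and 0 without a trend. The same 4 were among them in each except the last. The cause was not tested. In the fit within pairs each probe set has 1 residual degree of freedom, and on simulated data that fit called 9 unchanged probe sets.

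The count of lists, 6, was 3 with quantile normalization (2 of the 6, and the unfolded protein list), 3 without a trend, 4 with no filter, 7 with median centring, 8 with pseudocount 64, 9 with the upper 40% of probe sets and 5 with the mean of a gene's probe sets (4 of the 6). It was 0 with an estimated correlation, 0 by fry and 0 with the block and an estimated correlation. With arrays left out it ranged from 3 to 5, with 3 of the 6 each time. The others were the G2/M and the kinase inhibitor and p53 lists without CD9 replicate 2, and the mitochondrial list without LacZ replicate 2. In the replicate block 7 lists passed, the 6 and the synthetic smooth muscle list, and the block changed the call of no other list. The immediate early list passed under 13 of 15 alternatives and the YAP-TEAD list under 12, the ribosomal list under 9, the matrix list under 8, the G1/S list under 7 and the adhesion list under 6. The adjusted p of the immediate early list ranged from 2.74e-15 to 0.901. The ribosomal median was −0.028 with quantile normalization. With arrays left out, medians ranged from −0.035 to 0.42 for ribosomal, from −0.070 to 0.28 for matrix and from −0.35 to 0.018 for G1/S genes. Of the 24 other lists, 7 passed under at least 1 alternative: synthetic smooth muscle under 5, unfolded protein under 2, and G2/M, kinase inhibitors and p53, mitochondrial, calcium handling and endothelial markers under 1 each.

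The 509 probe sets changed 1.5-fold in both pairs became 214 with pseudocount 64, 1828 with no filter, 141 with the upper 40% and 79 at a fold limit of 2. The filter settings admit or drop dim probe sets, the fold limit drops smaller changes and the larger pseudocount shrinks folds, each by construction. With arrays left out, the log2 fold change ranged from −0.43 to 0.17 for Cd9, −0.14 to 1.56 for F3, −2.36 to 0.28 for Gdf15, −1.21 to 0.046 for Creld2 and −1.01 to 0.0063 for Ddit3, and no other named gene changed sign under any alternative. A group left with 1 array is assumed to vary like the other.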

Other observations

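The contrast between replicate numbers and the tests of RNA integrity and of dish handling were chosen only after the result was seen. The arrays differed more by replicate number, which was read as the transduction experiment, than by group. RNA quality went with the number too. The hexokinase 3'/5' ratio was 6.13 and 2.60 in CD9 and LacZ replicates 1, and 10.8 and 4.90 in replicates 2. The Gapdh ratio was 1.22 and 0.977, and 2.10 and 1.57. The actin ratio was higher in replicate 2 in the CD9 arrays only. Experiment, RNA quality and array batch cannot be told apart here. With the arrays split by replicate number, 890 probe sets passed limma, 682 higher in replicate 1 and 208 in replicate 2, and 7 gene lists passed camera. Mitochondrial respiratory chain genes had a median log2 difference of 0.44 (replicate 2 minus replicate 1; adjusted p = 0.000122) and ribosomal protein genes 0.46 (adjusted p = 0.00225), but the ribosomal difference was −0.07 after quantile normalization. Genes of G2/M and mitosis differed by 0.38 (adjusted p = 0.00428), heat shock proteins by 0.39 (adjusted p = 0.0155) and p53 targets and kinase inhibitors by 0.41 (adjusted p = 0.0265). Glycolysis and hypoxia genes differed by −0.41 (adjusted p = 0.00225) and immediate early genes by −0.30 (adjusted p = 0.0131). The other 6 lists kept their sign after quantile normalization and median centring, and heat shock and p53 genes did not pass after quantile normalization (adjusted p = 0.0536 each). None of the 7 passed with an estimated correlation (adjusted p = 0.853 to 0.927).

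The 4 arrays allow 3 splits, too few for a share under 0.05. The real split gave 0 probe sets and 6 lists, the split by replicate number 890 and 7, and the crossed split 0 and 0. At an unadjusted p under 0.05 the counts were 227, 4424 and 115. The split by number points to a structure of the samples, and the fit within pairs, which takes it out, gave 4 probe sets and 7 lists, but 0 probe sets without an intensity trend and 0 lists with an estimated correlation (smallest adjusted p = 0.743).

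Immediate early genes were higher in the CD9 arrays as a list, with 24 of 32 members higher and 8 lower. The list passed camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.901) or by fry (adjusted p = 0.736). Those 2 tests have little power with 2 arrays per group. Over all genes 0 members passed without the block and 3 with it. A hypothesis is that CD9 raises or prolongs their response to adhesion on fibronectin. This was not tested, since the arrays hold 1 time point and no cells kept off fibronectin. Brightness-dependent scaling alone is argued against, since the list's median lay at percentile 100 among 10000 lists matched on signal, and 0 of them were as high. The median also stayed at 0.35 after quantile normalization. The random lists draw genes independently, while this list had an estimated correlation of 0.124, so the percentile may make its median look rarer than it is. RNA integrity stays open: the list was lower in replicate 2 (−0.302 on the log2 scale, bootstrap 95% −0.447 to −0.0853, against 0.103 for all genes), where the Gapdh and hexokinase 3'/5' ratios were higher in both groups, but the number also marks separate experiments. Handling of the dishes before lysis also stays open: the list's median absolute log2 difference was 0.439 between the LacZ arrays, 0.394 between the CD9 arrays and 0.457 between the groups, but the values within a group hold the difference between experiments too, and handling would have to act the same way in both pairs, in which 22 of 32 members were higher.

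Lists of abundant genes were higher in the CD9 arrays as deposited, and brightness-dependent scaling may account for some of them. After quantile normalization the ribosomal list was not higher (−0.03). The matrix (0.07, camera adjusted p = 0.910) and adhesion lists (0.01, adjusted p = 0.826) did not pass then, and the YAP-TEAD list did (0.18, adjusted p = 0.0266). With an estimated correlation none of these lists passed (adjusted p = 0.901 each). As deposited, the ribosomal median lay at percentile 21.2 among lists matched on signal, the focal adhesion and actin median at 55.4 and the matrix median at 92.5, within the central 95% of such lists. Besides the immediate early and YAP-TEAD lists, synthetic smooth muscle (98.6) and calcium handling (97.6) lay above that range. Unfolded protein (0.105), G1/S (1.3), glycolysis (2.1) and matrix proteases (2.31) lay below it. The random lists draw genes independently, so they do not hold the correlation between genes of a real list. The YAP-TEAD and MRTF-SRF median lay at percentile 100, so scaling by brightness alone is argued against for that list. RNA integrity stays open for it, since its median was 0.16 in replicate 2 minus replicate 1, against 0.103 for all genes, and this list did not pass by number (adjusted p = 0.907). An effect of CD9 stays open as a hypothesis.

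More probe sets were lower than higher in the CD9 arrays in both pairs, 76.2% of 509 (exact binomial 95% interval 72.3 to 79.9, treating probe sets as independent). Each pair alone also had more lower than higher, 1283 against 801 in pair 1 and 2942 against 2063 in pair 2. With these counts, independent pairs would give 203 lower and 88.7 higher, so an even split is not what independent pairs would give. After quantile normalization the lower share was 62.1% (57.4 to 66.8), smaller than as deposited and still more than an even split, so how much of the excess comes from scaling cannot be told apart from real decreases by this test. Median centring gave 53.01% (48.3 to 57.7), but a shift of all probe sets by 0.12 moves the share by construction and decides nothing. In 152 genes a dimmer probe set was lower in both pairs, at a median log2 fold change of −0.99, while the median of their brightest probe sets was 0.0253 (bootstrap 95% −0.0179 to 0.0670), against 0.03 over all 2720 genes with several probe sets. These are the values predicted for changes confined to single dim probe sets, in place of changes of whole transcripts. The dimmer probe sets were selected for being lower, however, and noise at dim probe sets would give the same values. The test therefore cannot tell a change at single probe sets from noise. In the 27 genes whose dimmer probe set was higher in both pairs, the brightest had a median of −0.02, so the test does not bear on why more were lower.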
